A study of Bos taurus with 4 samples.

How the data were processed

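Gene expression was measured in bovine gamma delta T cells, a lymphocyte class that makes up a large part of the blood T cells of young ruminants. Per the labels' protocols, the cells were sorted from peripheral blood of calves aged 1 to 6 months to a purity of over 97%, rested overnight, and stimulated for 4 h with an aqueous apple polyphenol extract (APP) or with phosphate-buffered saline (PBS). The series' design text gives 42.2 µg/ml as the APP concentration and calls the 2 calves neonatal. Per the labels' protocols, biotin-labelled cRNA was made from 15 µg of total RNA and hybridised to an Affymetrix bovine array. The 4 arrays are PBS and APP for calf 301 and PBS and APP for calf 303. Each array was assigned to its treatment and calf from its title. The source of the extract beyond its name, its endotoxin content, the scan dates and any array batch are not given in the sources used here, so an array batch that followed the treatment could not be told apart from it.

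The authors summarised probes into probe sets with RMA, per the submitters' processing notes, which give no version and no background or scaling options. The deposited values are linear ratios, not log2 intensities. The sources used here do not say so, and the unit was found from the values. Once each array was multiplied by 1 factor (1.003 and 1.019 for PBS and APP of calf 301, 0.998 and 1.009 for PBS and APP of calf 303), the mean of the middle values of every probe set was 1 to within 0.00054, across all 24128 probe sets. The values therefore are each probe set's signal over its own median across the 4 arrays, with a minor factor per array. The median ratio per array was 0.992, 0.991, 0.994 and 0.995 for PBS 301, APP 301, PBS 303 and APP 303, and the ratios ran from 0.0264 to 6.814. Differences between arrays are kept on this scale, but the level of a probe set is lost, so that it is unknown which probe sets lay near background in one or both treatments. A fold change of a probe set near background is compressed, and no level could be set against another. No depth exists for arrays, and their number, 2 per treatment, limits the precision.

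The ratios were log2 transformed and used without further normalization. All 112 Affymetrix control probe sets were left out of the tests, and 24016 probe sets were tested. Gene names came from a platform annotation table, and its Entrez identifiers were updated through a RefSeq gene table of the bovine assembly ARS-UCD2.0, which was used for names only. Of the tested probe sets, 13292 had 1 gene symbol, 86 had several and 10638 had none in that table. Of the 13292 with 1 gene, 13263 were found by identifier in the RefSeq table and 29 kept the older symbol. The named probe sets covered 9155 genes, 6242 of them by 1 probe set and 2913 by several. The log2 values of all probe sets of a gene were averaged. Where those of a gene given with its change differed by more than 0.5 on the log2 scale, in the comparison it is named for, their values or range are given. No column of another sample was present.

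The treatment was tested with limma 3.58.1 (lmFit and eBayes, two-sided) in R 4.3.3, with the calf as a block, over probe sets and again over genes, with Benjamini-Hochberg adjustment and a threshold of 0.05. The calf was the block because the titles name the same 2 animals in both treatments. As a check of this pairing, the difference between the calves was computed within each treatment, and it correlated between PBS and APP with r = 0.514 across probe sets. The fit had 1 residual degree of freedom, and the prior degrees of freedom borrowed across features were 5.19 for probe sets and 5.86 for genes. The difference between the calves was the other term of the same fit. Changes of at least 2-fold in the same direction in both calves were also counted, which needs no estimate of spread. With 2 arrays against 2, an exact permutation test of a single value cannot go below p = 0.33, and no such test was made.

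Before the data were examined, 23 gene lists, the tests, the alternatives and the rule for the genes to be named were fixed. The named genes are the 12 with the largest rise and the 12 with the largest fall past the threshold and the same in direction in both calves, up to 4 members per list with the largest change, 8 genes of innate effector function named in any case (ITGAM, CSF2, CXCL8, IFNG, TNF, IL2RA, CD69 and 1 that is not reported here), and the 3 genes per direction that differed most between the calves. Other members of a list that are named, mostly those that went against the rest of the list, were chosen after their values had been seen. The lists hold 643 different gene symbols, of which 456 were matched by symbol and 4 by a synonym, while 183 had no probe set named here and were not analysed here. Lists were tested with camera at a preset inter-gene correlation of 0.01, which asks whether the genes of a list moved more than the other genes did. Camera with an estimated correlation and fry, which asks whether the genes of a list moved on balance in 1 direction, were alternatives. With 1 residual degree of freedom the estimated correlation is poorly determined. Camera in that setting also takes its p-value from a t distribution with that 1 degree of freedom, so that only an extreme value could pass. A list that does not pass there is therefore not shown to have failed. At the preset correlation camera takes its degrees of freedom from the number of genes. Those p-values therefore do not measure variation between calves, and they rest on the preset value.

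The plan was departed from in 3 places, because the values proved to be ratios to each probe set's median. A variance trend on the mean was planned as the main setting and changed places with the single prior variance, planned as an alternative, since the mean of such ratios carries no level. A gene was to be represented by its brightest probe set, and the mean of its probe sets, listed among the alternatives, was used instead. List members were therefore counted after adjustment over all genes. The filter on dim probe sets could not be applied. Apart from these, the fits of the calf comparison without the replicate block had been written down as treatment alone, which holds no calf difference, and were run with the calf as the only term. EEF1A1, Cyph, eIF-4E and GST were added to the transcripts planned as signs of RNA quality after the data had been seen. Other alternatives were the fit without the replicate block, which called 2473 probe sets as higher and 4273 as lower where the blocked fit called 3919 and 5672, a filter on probe sets shared between transcripts, a repeated quantile normalization, median centring, a lower fold limit, and leaving out each array or each calf. Scaling to the hybridization control probe sets of bioB, bioC and bioD, without those of the control cre, was added after the data had been seen. Under it the median change of all probe sets moved from 0.022 to -0.829 on the log2 scale, so every direction given here is relative to the bulk of the probe sets on the array, and the amount of RNA per cell was not measured.

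The test was tried on simulated data in 20 draws of 24016 probe sets, with the calf difference of the real arrays, noise drawn from the fitted prior, and 200 probe sets changed by known amounts, 50 of each size. For the APP comparison, the median share recovered over the draws was 4% at a log2 change of 0.5 (0 to 22%), 92% at a change of 1 (72 to 100%), 100% at a change of 2 (98 to 100%) and 100% at a change of 4. The share of false calls among all calls had a median of 9.9% and ran from 2.6 to 23.8%, above the nominal 5% in 15 of the 20 draws. The prior degrees of freedom, drawn at 5.19, were estimated at 4.64 to 10.99 in those draws. With as many changed probe sets as were called in the data (9591), each with the size measured, the share of false calls was 3.3% (2.9 to 4.3%). Of the changed probe sets, 89% were recovered. Uncalled probe sets were given no change there. The noise of every draw was independent between probe sets, so errors shared across an array were not simulated, and these shares hold under those assumptions only.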

Results

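Transcripts of sorted bovine gamma delta T cells were profiled on 4 Affymetrix arrays after 4 h with an apple polyphenol extract (APP) or with buffer alone (PBS). Cells of 2 calves, 301 and 303, were each divided between the treatments, giving 2 arrays per group. Values are log2 ratios to each probe set's own median over the 4 arrays, so changes between arrays can be read and levels cannot. Genes are given with the change in each calf, with the mean and SD over the 2 calves, or with the mean alone, and for the APP changes given as a mean alone limma's standard error lay between 0.095 (HSP90AB1) and 0.115 (KLRB1).

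The first comparison addressed which transcripts of these innate-like lymphocytes respond to APP. CSF2, which encodes the growth factor GM-CSF, rose the most of all named genes, 85.1-fold on average (log2 change 6.41 ± 0.89, SD, n = 2 calves, with 5.78 in calf 301 and 7.04 in calf 303). PLAU, the urokinase plasminogen activator, rose 32.9-fold (5.04 ± 0.32), the carbonic anhydrase gene CA2 26.1-fold (4.71 ± 0.09) and CDKN1A, an inhibitor of cyclin-dependent kinases, 25.8-fold (4.69 ± 0.12). IL2, the T cell growth factor, rose 17.9-fold, by 3.16 in calf 301 and 5.17 in calf 303 on the log2 scale, the widest gap between the calves among the 12 largest rises. The others of these 12 were SPRY1, an inhibitor of growth factor signalling (4.59 ± 0.44), NOCT (4.52 ± 0.08), the junctional adhesion molecule JAM2 (4.22 ± 0.80), TMEM88 (4.16 ± 0.25), the protein kinase C substrate PLEK (4.14 ± 0.16), the transcription factor BHLHE40 (3.82 ± 0.13) and the octamer-factor coactivator POU2AF1 (3.81 ± 0.51). The probe sets of BHLHE40 differed in size, with changes of 2.25 and 5.39. Adjusted p in limma's test with the calf as a block ran from 2.36e-06 (CA2) to 0.000181 (IL2) among these 12.

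The falls were smaller. MAP2K6, a kinase upstream of p38, fell 9.16-fold (log2 change -3.20 ± 0.24, SD, n = 2 calves) and CDC42EP3, an effector of the small GTPase CDC42, fell 8.10-fold (-3.02 ± 0.02). Next came HPS3, needed for lysosome-related organelles (-2.78 ± 0.13), the Fas apoptosis inhibitor FAIM (-2.72 ± 0.19), PTER (-2.70 ± 0.46), the lysophosphatidic acid receptor LPAR6 (-2.64 ± 0.34), SFT2D2 (-2.64 ± 0.11), the translation regulator IMPACT (-2.64 ± 0.22), TMEM106C (-2.61 ± 0.25), ARFGAP3 (-2.52 ± 0.26), DTWD1 (-2.51 ± 0.02) and TTC13 (-2.50 ± 0.60). Adjusted p in limma's test lay between 6.92e-06 and 7.03e-05 for these 12. Among probe sets with no gene name in the table used here, 1378 rose and 2302 fell with the largest changes at 5.87 and 4.12 among the rises and at -3.61 and -3.52 among the falls.

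**Figure D1:**
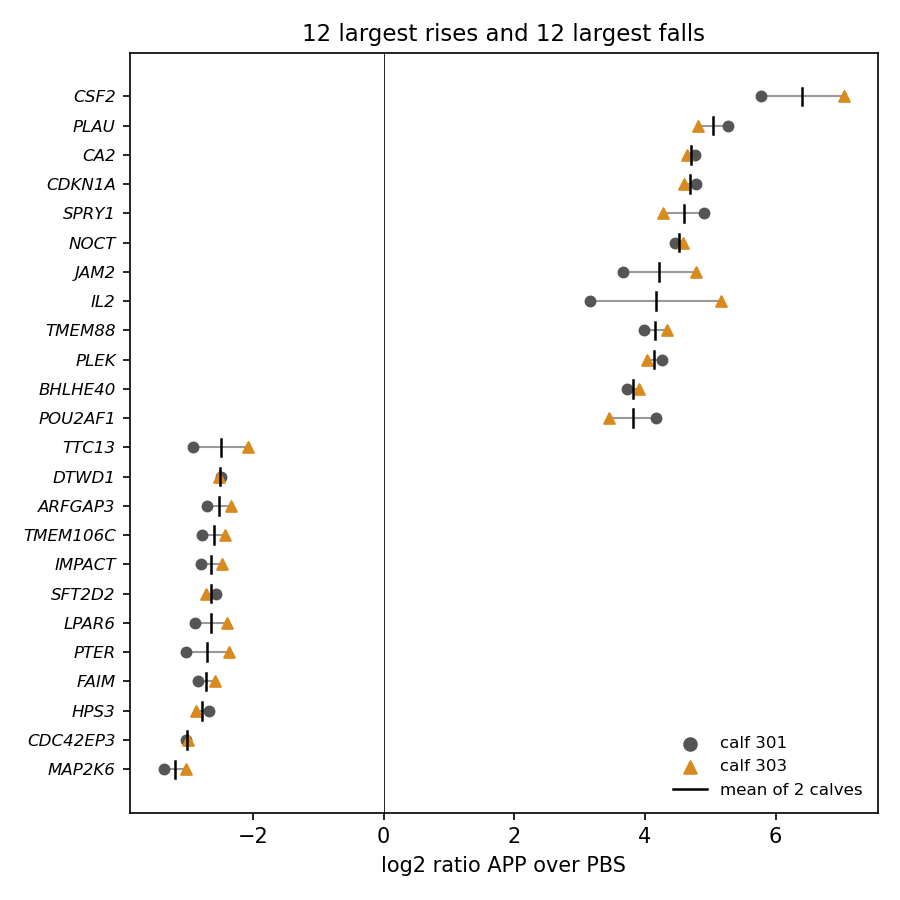
Log2 ratio of APP over PBS (x axis) for the 12 named genes with the largest rise and the 12 with the largest fall, with calf 301 as circles, calf 303 as triangles and the mean of the 2 calves as a bar. CSF2 stands at 5.78 and 7.04, and the lowest mean is that of MAP2K6 at -3.20.

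The change was broad. Of 24016 probe sets, 3919 (16.3%) rose, 5672 (23.6%) fell and 14425 did not pass an adjusted p of 0.05. Of 9155 genes, 2104 (23%) rose and 2717 (29.7%) fell, the shares beside which the counts of list members below stand. At least 2-fold changes in both calves were rises for 704 probe sets and falls for 1545, and none went up in one calf and down in the other by that much. The changes of the 2 calves correlated across probe sets, which are not independent replicates (Pearson r = 0.906, Spearman rho = 0.816). Their SD was 0.677 in calf 301 and 0.658 in calf 303, against 0.268 (PBS) and 0.313 (APP) for the difference between the calves. Without the replicate block 2473 probe sets rose and 4273 fell, and 1399 genes rose and 2161 fell, so that rises were 36.7% of the probe sets called. The split between rises and falls depended on the scaling. Rises were 40.9% of calls as deposited. They were 2.8% (615 rises, 21653 falls) when arrays were scaled to the hybridization controls bioB, bioC and bioD, described at the end. In unblocked fits that left out 1 array, 1291 probe sets rose and 2973 fell without PBS 301, 2047 and 3453 without APP 301, 1155 and 2455 without PBS 303, and 2406 and 4281 without APP 303.

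**Figure D2:**
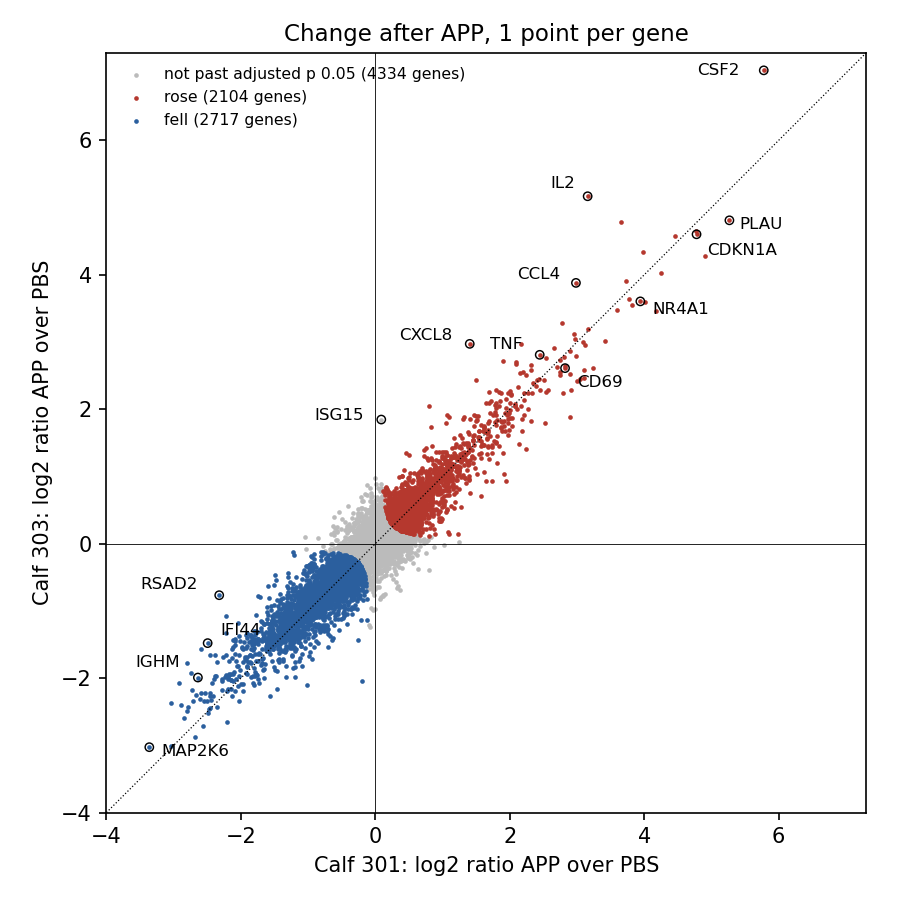
Log2 ratio of APP over PBS in calf 301 (x axis) and calf 303 (y axis), with 1 point per gene for 9155 genes, coloured by limma's adjusted p (2104 rose, 2717 fell), and the line of equal change dotted. The changes run along that line, and IL2, CXCL8 and ISG15 lie above it.

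Some cytokine transcripts rose and others did not. Of 31 measured cytokine genes, 12 rose, 4 fell and 15 did not pass the test (12 and 3 adjusted over the list alone). Beside CSF2 and IL2, TNF rose 6.18-fold (2.45 in calf 301 and 2.81 in calf 303) and IL13, a type 2 cytokine, rose 4.18-fold (2.07 and 2.05), with changes of 1.35 and 2.78 for its probe sets. IFNG, the gene of interferon gamma, changed by -0.06 and 0.01 in the calves (adjusted p = 0.838, limma), and IL6 by 0.02 on average (adjusted p = 0.872). The members that fell were IL18 (-1.67 in calf 301 and -1.40 in calf 303), LTB (-0.38), TNFSF8 (-0.14 and -0.59) and IL16 (-0.34, with -0.87 to -0.05 over its 3 probe sets). As a list the cytokines moved up against all other genes (camera adjusted p = 0.00398, adjusted p = 0.777 with an estimated correlation), with a median change of 0.19 that became -0.66 when scaled to the hybridization controls.

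Chemokine genes rose in 13 of 20 cases and fell in 1 (14 and 1 adjusted over the list alone). CCL4, which attracts T cells and monocytes, rose 10.8-fold (2.98 in calf 301 and 3.88 in calf 303), CXCL2, which attracts neutrophils, 5.92-fold (2.16 and 2.97), CCL20 5.38-fold (2.57 and 2.28) and CXCL16 5.27-fold (2.54 and 2.25). CXCL8, the main neutrophil attractant, rose 4.56-fold on average, by 1.41 in calf 301 and 2.97 in calf 303. The exception was the fall of CXCL12, the ligand of CXCR4 (-2.04 in calf 301 and -2.34 in calf 303). The list moved up (camera adjusted p = 0.000311, adjusted p = 0.777 with an estimated correlation), with a median of 0.41 that became -0.44 when scaled to the hybridization controls. Over the same arrays 10 of 23 monocyte and dendritic cell genes rose, CD68 by 1.90 and 2.71 in the calves.

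T cell activation and immediate early genes had the highest median change of the 23 lists, 1.12, or 0.27 when scaled to the hybridization controls. Of 31 measured, 24 rose, 1 fell and 6 did not pass (25 and 1 adjusted over the list alone). The orphan nuclear receptor NR4A1 rose 13.7-fold (3.77 ± 0.24, SD, n = 2 calves), the stress-responsive transcription factor ATF3 13.1-fold (3.71 ± 0.10), the costimulatory receptor TNFRSF18 8.03-fold (2.97 in calf 301 and 3.04 in calf 303) and CD83 7.40-fold (2.89 ± 0.14). The early activation antigen CD69 rose 6.58-fold (2.72 ± 0.15) and IL2RA, the alpha chain of the interleukin-2 receptor, 5.44-fold (2.44 ± 0.02). The member that fell was ICOS (-1.04 in calf 301 and -0.70 in calf 303). Camera gave an adjusted p of 2.98e-11 at the preset correlation, with genes and not calves as its units (adjusted p = 0.777 with an estimated correlation).

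Targets and inhibitors of NF-kappaB rose in 14 of 20 cases, with 1 fall and 5 that did not pass (15 and 1 adjusted over the list alone). The median was 0.98, or 0.13 when scaled to the hybridization controls. After PLAU, the largest rises were those of the inhibitor NFKBIA (8.20-fold, 3.04 ± 0.12, SD, n = 2 calves), the adaptor TRAF1 (7.37-fold, 2.88 ± 0.01) and the subunit gene NFKB2 (5.27-fold, 2.40 ± 0.43). SOD2, a mitochondrial superoxide dismutase, changed by -0.71 in calf 301 and -0.21 in calf 303 and was the member that fell. The list moved up by camera (adjusted p = 3.81e-07, adjusted p = 0.777 with an estimated correlation).

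Interferon-stimulated genes fell more often than they rose. Of 29 measured, 15 fell, 2 rose and 12 did not pass (16 and 3 adjusted over the list alone), with a median change of -0.40 that became -1.25 when scaled to the hybridization controls. IFI44 fell 3.96-fold (-2.49 in calf 301 and -1.48 in calf 303), with changes between -2.79 and -1.51 for its 4 probe sets. IFI44L fell 3.24-fold (-1.75 and -1.64), the guanylate-binding protein gene GBP4 3.01-fold (-1.76 and -1.42) and the antiviral gene RSAD2 2.92-fold (-2.32 and -0.77). The risers were IRF7 (0.43) and IFIT2 (0.31), and ISG15 changed by 0.09 in calf 301 and 1.85 in calf 303 (adjusted p = 0.0527, limma). The median was -0.60 in calf 301 and -0.29 in calf 303, and 27 of the 29 genes lay higher in the change of calf 303, a difference that was not tested. The list moved down by camera (adjusted p = 0.0187, adjusted p = 0.827 with an estimated correlation), which did not hold without the APP array of calf 301.

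Among stress lists, 16 of 27 unfolded protein and amino acid response genes rose and 2 fell (the same counts adjusted over the list alone). PPP1R15A, which directs dephosphorylation of the translation factor eIF2 alpha, rose 6.20-fold (2.75 in calf 301 and 2.51 in calf 303), DDIT4, an inhibitor of mTOR signalling, 3.46-fold (1.97 and 1.61), the mitochondrial folate enzyme MTHFD2 3.18-fold (1.68 and 1.66) and CHAC1, which degrades glutathione, 2.79-fold (1.70 and 1.27). Those that fell were PDIA4 (-0.75, with -1.20 to -0.08 over its 3 probe sets) and SEL1L (-0.52). The list moved up (camera adjusted p = 0.000311, adjusted p = 0.777 with an estimated correlation), and its median of 0.44 became -0.41 when scaled to the hybridization controls. Heat shock protein genes rose in 12 of 21 cases and fell in 3 (13 and 3 adjusted over the list alone), each by less than 2-fold in the mean of the calves. HSPH1 rose by 1.08 in calf 301 and 0.80 in calf 303 (0.48 to 1.29 over its 4 probe sets), HSPA9 by 0.84 (0.42 and 1.26 for its probe sets) and HSP90AB1 by 0.83, while the cochaperone gene BAG3 fell by 0.94, SERPINH1 by 0.42 and HSPB1 by 0.37. The probe sets of HSPB1 moved in opposite directions (-1.11 and 0.36). This list moved up as well (camera adjusted p = 0.00967, adjusted p = 0.777 with an estimated correlation), and its median of 0.39 became -0.46 when scaled to the hybridization controls, with HSPA9 at -0.01 and HSP90AB1 at -0.03.

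Genes of the NRF2 antioxidant programme, which polyphenols are often studied for, moved both ways. Of 26, 12 rose and 7 fell (the same counts adjusted over the list alone), and the list did not pass the test (camera adjusted p = 0.257). SLC3A2, a chain of several amino acid transporters, rose 5.54-fold (2.47 ± 0.05, SD, n = 2 calves) and the autophagy receptor SQSTM1 3.50-fold (1.80 ± 0.47), while catalase (CAT) fell 2.51-fold (-1.32 ± 0.07) and LOC281806, listed with GSTP1 as a synonym, 2.20-fold (-1.14 ± 0.22). Also among the 12 that rose were NQO1, GCLC, GSR, TXN, TXNRD1, SRXN1 and OSGIN1. The other members that fell were TKT, ABCC1, EPHX1, SOD1 and GPX1. GCLM did not pass, nor did HMOX1, heme oxygenase, which changed by 0.64 in calf 301 and -0.37 in calf 303 (adjusted p = 0.627, limma). In the metal response list, 5 of 8 rose and 2 fell (6 and 2 adjusted over the list alone, camera adjusted p = 0.13), with the transferrin receptor TFRC up 6.66-fold (2.74 in calf 301 and 2.73 in calf 303) and MTF1 up by 0.54, against falls of SLC11A2 (-0.62 and -1.41) and ACO1 (-0.59). MTF1 stood at -0.31 when scaled to the hybridization controls. Of 9 aryl hydrocarbon receptor genes, 3 fell and 1 rose (the same adjusted over the list alone). TIPARP fell 2.48-fold (-1.31 in each calf), LPCAT2 by 0.57 and AHR, the receptor, by 0.46, while ALDH3A1 rose by 0.35, or stood at -0.50 when scaled to the hybridization controls. CYP1A1 changed by 0.13 (adjusted p = 0.288). The median of these 9 was 0.06, their mean -0.15, and the test, which ran downward, did not pass (camera adjusted p = 0.867).

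Metabolic and growth lists were mixed and none passed the list test. Of 31 hypoxia and glycolysis genes, 14 rose and 8 fell (14 and 9 adjusted over the list alone, camera adjusted p = 0.11). VEGFA rose 5.18-fold (2.37 ± 0.25, SD, n = 2 calves), and the glycolytic enzyme genes PFKP (1.54 ± 0.11) and PKM (1.16 ± 0.29) rose, while EGLN1, an oxygen-sensing hydroxylase, fell (-1.34 ± 0.27). Of 25 sterol genes, 10 rose and 5 fell (the same adjusted over the list alone, camera adjusted p = 0.0872), with ACAT2 (1.14 ± 0.14) and SQLE (0.92 ± 0.23) up and INSIG2 (-1.21 ± 0.15, with -1.52 to -0.90 over its 3 probe sets) and EBP (-1.19 ± 0.04) down. That list passed without the APP array of calf 301 (adjusted p = 0.0446). Of 34 cell cycle genes, 7 rose and 10 fell (the same adjusted over the list alone, camera adjusted p = 0.867). Beside CDKN1A, the cyclin gene CCND2 rose (1.68 ± 0.23), while thymidine kinase TK1 (-1.72 ± 0.27) and CCND3 (-1.26 ± 0.09) fell. The median of this list was -0.01, its mean 0.05, and its test ran downward. Of 15 apoptosis and p53 target genes, 7 rose and 5 fell (the same adjusted over the list alone, camera adjusted p = 0.285). GADD45B (2.14 ± 0.20), the survival gene BCL2L1 (1.92 ± 0.20) and the death receptor gene FAS (0.84 ± 0.39) rose and CCNG1 (-0.76 ± 0.06) fell, and FAS stood at -0.01 when scaled to the hybridization controls.

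Cytotoxic granule and killer receptor genes rose in 7 of 13 cases and fell in 1 (the same adjusted over the list alone). CRTAM, a receptor of activated cytotoxic lymphocytes, rose 14.02-fold (4.02 in calf 301 and 3.60 in calf 303), followed by CTSC (0.80 and 1.08), perforin (PRF1, 0.72) and SRGN (0.54), while KLRB1 fell by 0.40. GZMB, the gene of granzyme B, changed by 0.03 (adjusted p = 0.85). The list moved up (camera adjusted p = 0.0187, adjusted p = 0.777 with an estimated correlation), which did not hold without the APP array of calf 303. When scaled to the hybridization controls its median of 0.30 became -0.55, PRF1 stood at -0.13 and SRGN at -0.31.

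Adhesion and homing genes moved both ways, 7 of 21 up and 5 down (the same adjusted over the list alone, camera adjusted p = 0.539). S1PR1, the receptor that guides lymphocytes out of tissues, fell 3.75-fold (-2.08 in calf 301 and -1.74 in calf 303, with -2.25 and -1.56 for its probe sets) and SELPLG, the P-selectin ligand, 2.25-fold (-1.16 and -1.17), while the chemokine receptor genes CXCR6 (1.67 and 1.45) and CCR4 (1.17 and 1.57) rose. ITGAM, a chain of the integrin Mac-1, changed by -0.03 and -0.21 in the calves (adjusted p = 0.349, limma). Of 16 pattern recognition genes, 4 rose and 5 fell (the same adjusted over the list alone, camera adjusted p = 0.705). The signalling kinase IRAK4 fell 2.86-fold (-1.53 and -1.50), the double-stranded RNA sensor TLR3 2.30-fold (-1.33 and -1.06, with -1.46 to -0.94 over its 3 probe sets) and the adaptor TICAM2 1.68-fold (-0.72 and -0.77), while SCARB1 rose 1.92-fold (0.97 and 0.91). That list had a median of 0.01 and a mean of -0.16.

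Of 18 gamma delta T cell identity genes, 8 fell and 3 rose (the same adjusted over the list alone, median -0.15, camera adjusted p = 0.257). CD7 fell 2.98-fold (-1.60 in calf 301 and -1.56 in calf 303), CD163L1, of the scavenger receptor family that holds the WC1 coreceptors, 2.11-fold (-1.20 and -0.96), WC1.3 1.82-fold (-0.92 and -0.80) and the transcription factor TCF7 1.62-fold (-0.76 and -0.63). WC1 genes are near-identical copies, and their probe sets may share signal. The risers were CD5 (0.62), LEF1 (0.56) and IL2RG (0.30). CD7, TCF7, CD5, LEF1 and IL2RG are expressed by other T cells too, so their changes are not particular to gamma delta identity.

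Of the 5 lists for cell types the sort could still hold, that of monocytes and dendritic cells passed the list test at the preset correlation and the other 4 did not. Of 8 B cell genes, 5 fell and 1 rose (5 and 2 adjusted over the list alone, median -0.68, camera adjusted p = 0.285): the immunoglobulin heavy chain gene IGHM fell 4.98-fold (-2.64 in calf 301 and -1.99 in calf 303), JCHAIN 2.52-fold (-0.95 and -1.72) and BLK 2.06-fold (-0.95 and -1.13), with CD79A and MS4A1 below 2-fold, and the riser was POU2AF1. The probe sets of MS4A1 changed by -1.08 and -0.04. Of 23 monocyte and dendritic cell genes, 10 rose and 2 fell (the same adjusted over the list alone). CD68, a lysosomal glycoprotein gene, rose 4.95-fold (1.90 and 2.71), FCN1 by 0.67 and 0.58 and C1QB by 0.40 and 0.75, while CTSS fell by 0.56 and LYZ2 by 0.31. The 4 probe sets of LYZ2 ran from -1.34 to 0.13. The list moved up (camera adjusted p = 0.0134, adjusted p = 0.777 with an estimated correlation), and when scaled to the hybridization controls its median of 0.23 became -0.62, FCN1 stood at -0.23 and C1QB at -0.28. Of 15 neutrophil genes, 3 rose (1 adjusted over the list alone) and none fell (camera adjusted p = 0.0872, or 0.0384 without the APP array of calf 303). They were MMP9 (0.66 in calf 301 and 0.47 in calf 303), PGLYRP1 (0.33) and CATHL2 (0.32), and all 3 lay below 0 when scaled to the hybridization controls (-0.29, -0.52 and -0.54). Of 11 alpha beta T and NK cell genes, 2 rose and 1 fell (1 and 1 adjusted over the list alone, camera adjusted p = 0.781). CD8A rose by 1.40 in calf 301 and 0.75 in calf 303 and FOXP3 by 0.54 and 0.15, and CD8B changed by -0.63 and -0.65. FOXP3 stood at -0.50 in the mean when scaled to the hybridization controls. The median of that list was -0.01 and its mean 0.07. Of 13 platelet and erythrocyte genes, GYPC fell by 0.57 and the other 12 did not pass, with SLC4A1 at 0.62 and 0.12 in the calves (adjusted p = 0.0554) or at a mean of -0.49 when scaled to the hybridization controls (0 and 1 adjusted over the list alone, camera adjusted p = 0.653).

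**Figure D3:**
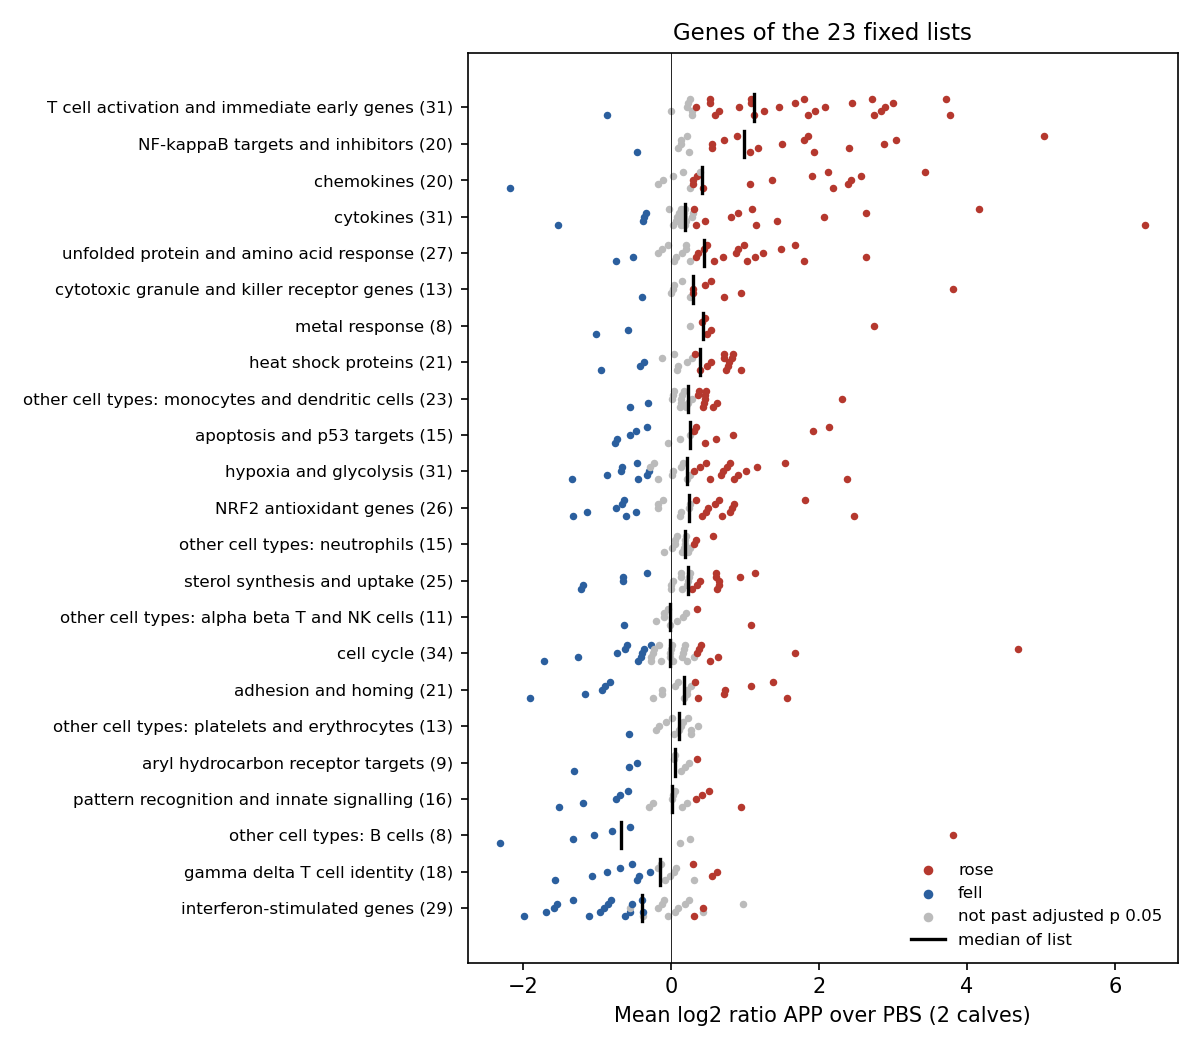
Mean log2 ratio of APP over PBS in the 2 calves (x axis) for each measured gene of the 23 lists (rows, number of genes in brackets, ordered by mean), coloured by limma's adjusted p, with the list median as a black bar. The highest medians are 1.12 for T cell activation genes and 0.98 for NF-kappaB genes, and the interferon-stimulated genes have a median of -0.40.

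The second comparison set the calves against each other, with treatment as the other term. At an adjusted p of 0.05 in limma's test, 130 probe sets were higher and 27 lower in calf 303, against 9591 that changed with APP. In a fit with the calf as its only term, limma called 0 probe sets, and 292 passed an unadjusted p of 0.05. That fit leaves the treatment difference in its residual, so its count of 0 is no sign against the calf differences. OGN, a small proteoglycan, was 6.83-fold higher in calf 303 (log2 difference 2.45 with PBS and 3.09 with APP), XIST, the RNA that coats the inactive X chromosome, 6.61-fold (2.93 and 2.52) and TRGC6, a T cell receptor gamma constant gene, 6.28-fold (2.38 and 2.92). The 6 probe sets of XIST differed by -0.29 to 5.75. The sex of the calves is not among the sample details used here, so sex and other differences between the 2 animals cannot be told apart. RNF181, IGFLR1 and TMBIM1 were 2.43-fold, 2.38-fold and 2.37-fold higher in calf 301. The number of such probe sets was 31 after a repeated quantile normalization, 1519 with a variance trend and 1639 when scaled to the hybridization controls.

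Array controls also differed between the treatments. The 14 probe sets for the bacterial hybridization controls bioB, bioC and bioD, which are added to the hybridization mix and not made by the cells, were all higher on the APP array of both calves, with a median log2 difference of 0.89 (0.79 in calf 301 and 0.97 in calf 303). The 24 probe sets for the poly-A controls dap, lys, phe and thr were all higher too, with a median of 0.48 (0.68 and 0.30). The 4 probe sets of the hybridization control cre differed by 0.22, and 47 other control probe sets named by an accession by 0.08. As a sign of RNA quality, the 3' minus 5' log2 value of GAPDH, relative to the median array, was -0.06 (PBS) and -0.18 (APP) in calf 301 and 0.07 and 0.06 in calf 303, that of beta actin was 0.14 and -0.18 in calf 301 and -0.04 and -0.01 in calf 303, and that of EEF1A1 was 0.05 and -0.26 in calf 301 and 0.14 and -0.05 in calf 303. The value of EEF1A1 was thus lower on the APP array of both calves, as was GAPDH's (0.066 and 0.063 in calf 303). That of beta actin was lower in calf 301 only. The bovine controls Cyph, eIF-4E and GST also have 3' and 5' probe sets. Their 3' minus 5' value was lower with APP in both calves. Mean log2 changes of those 3' and 5' probe sets were 0.021 and 0.335 (Cyph), 0.859 and 0.951 (eIF-4E) and -0.034 and 0.12 (GST). A difference in RNA quality that followed the treatment is not excluded.

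**Figure D4:**
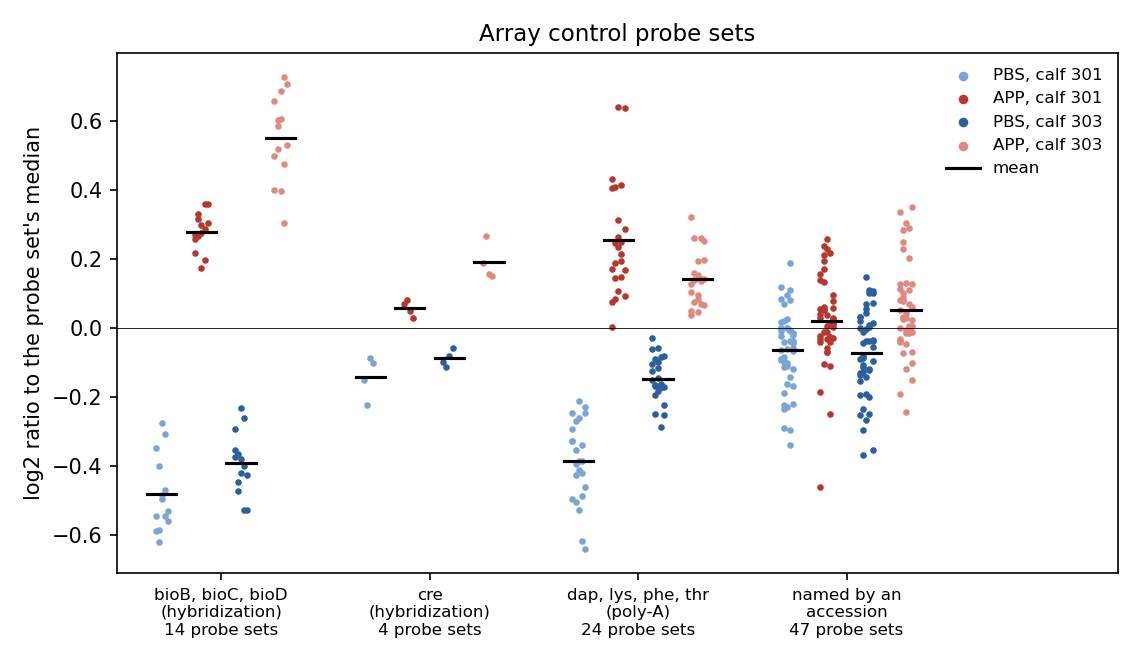
Log2 ratio of each control probe set to its median over the 4 arrays (y axis), by control class (x axis) and array (colours), with the class mean as a bar. The mean of the bioB, bioC and bioD probe sets is -0.48 and -0.39 on the PBS arrays and 0.28 and 0.55 on the APP arrays of calves 301 and 303.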

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

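The tests of this part were chosen after the results had been seen. The probe sets of the hybridization controls bioB, bioC and bioD were higher on the APP array of both calves, by a median of 0.893 on the log2 scale (1.86-fold), a signal in data outside the measured transcripts. The poly-A controls were higher by a median of 0.482, by 0.675 in calf 301 and 0.305 in calf 303.

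A rise of probe sets with little signal in general is a possible explanation of the hybridization control pattern. The 47 control probe sets named by an accession changed by a median of 0.082, with an upper quartile of 0.194 and a highest value of 0.576. The 3 trpn control probe sets changed by a median of -0.011 (-0.023 to 0.112). It is unknown which of all these have little signal, so this stays open. Less signal from the sample's RNA on the APP arrays, which normalization to equal distributions would turn into a higher ratio of the added controls, may also account for it. The cre control of the same mix rose by only 0.22, but levels are not kept, and a bright probe set may be compressed, so that this value does not decide. The poly-A controls are not part of the hybridization mix, and all 24 of their probe sets were higher on the APP array of both calves. A different amount of that mix alone would not account for their rise. For bioB, bioC and bioD, a different amount of mix and an effect of APP on the RNA content of the cells remain possible. These cannot be told apart from the other explanations with 1 array per calf and treatment.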

How the results depend on the processing

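Scaling to the hybridization controls and its values were chosen after the data had been seen. The other alternatives were planned, except that the calf comparison without the block was planned with the treatment as its term and run with the calf. The filter on dim probe sets was not run, because the ratios keep no levels, which also leaves signal over background unknown. Where no cause is given below, the cause was not tested.

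Without the replicate block 2473 probe sets rose and 4273 fell, 1399 genes rose and 2161 fell, and 0 probe sets (292 at an unadjusted p under 0.05) differed between the calves in limma's fit with the calf as its only term, whose residual holds the treatment. All of its 6746 APP calls were among the 9591 of the blocked fit, and it changed the call of no list. The calf comparison gave 1519 probe sets with a variance trend and 31 after a repeated quantile normalization. With the variance trend, planned as the main setting, 11309 probe sets were called for APP, of which 44.2% rose. Of these calls, 9436 were among the 9591 of the fit used here, in the same direction. At a limit of 1.5-fold in both calves, 1538 probe sets rose, 3299 fell and 1 moved in opposite directions.

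Scaled to the hybridization controls, which moves the median of all probe sets to -0.829, 615 probe sets rose and 21653 fell, 286 genes rose and 8182 fell, 183 probe sets rose and 6644 fell by 2-fold in both calves, and 1639 differed between the calves. List medians moved to 0.267 (activation genes) and 0.129 (NF-kappaB) and turned to -0.663 (cytokines), -0.44 (chemokines), -0.464 (heat shock proteins), -0.413 (unfolded protein response), -0.553 (cytotoxic genes) and -0.62 (monocytes and dendritic cells). Named genes that changed sign were HSPA9 (-0.013), HSP90AB1 (-0.026), MTF1 (-0.308), ALDH3A1 (-0.5), FAS (-0.009), PRF1 (-0.134), SRGN (-0.308), FCN1 (-0.229), C1QB (-0.279), MMP9 (-0.285), PGLYRP1 (-0.519), CATHL2 (-0.536), FOXP3 (-0.503) and SLC4A1 (-0.485). The common shift of the arrays in this scaling accounts for these. Only bioB, bioC and bioD entered it, with a median rise of 0.893. The control cre of the same mix, higher by 0.22, was left out, and scaling to it was not run. The size of the shift thus depends on the controls chosen. The cell cycle list, not past the test, moved up at adjusted p = 0.58, and at 0.9 without probe sets shared between transcripts.

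Leaving out 1 array without the block leaves 1 array in a group, assumed to vary like the others. It gave 1291 rises and 2973 falls (genes 794 and 1516) without PBS 301, 2047 and 3453 (1115 and 1720) without APP 301, 1155 and 2455 (745 and 1305) without PBS 303, and 2406 and 4281 (1292 and 2012) without APP 303, with 0 calf calls in each (96 to 197 probe sets at an unadjusted p under 0.05). Fewer samples enter these fits, and the calf fits, with the calf as their only term, hold the treatment difference in their residual. Adjusted p for interferon-stimulated genes was 0.0715, for sterol genes 0.0446 and for platelet genes, in the other direction, 0.904 without APP 301. For cytotoxic genes it was 0.0665, for neutrophil genes 0.0384 and for aryl hydrocarbon receptor genes, in the other direction, 0.967 without APP 303. CD8B turned to 0.505 without APP 301 and 0.512 without PBS 303, where the calves, which differ in CD8B, are no longer balanced. IFNG was 0.006 without APP 301, and -0.057 in calf 301 and 0.006 in calf 303 alone.

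With an estimated correlation, camera called 0 of the 23 lists at adjusted p under 0.05 and 0 at an unadjusted p under 0.05 (smallest 0.0782). Adjusted p was 0.777 for 8 of the 9 lists called at the preset correlation and 0.827 for interferon-stimulated genes. Fry called 2 lists, activation genes (0.0174) and pattern recognition genes (0.0174, not called by camera), and gave 0.0526 for NF-kappaB, 0.113 for cytokines, chemokines and heat shock proteins, 0.198 for interferon-stimulated genes, 0.101 for unfolded protein genes, 0.0883 for cytotoxic genes and 0.0881 for monocyte and dendritic cell genes. In the other direction from camera, it gave 0.113 for the cell cycle and 0.943 for alpha beta T and NK cells. No list changed its call under median centring, quantile normalization or the variance trend.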

Other observations

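The list tests between the calves, the tests of the endotoxin response genes and of the class II genes, and the choice of genes in the first 2 paragraphs were made after the results had been seen, while limma's fits were planned. Some further genes with large rises were picked one by one, and no group of them was tested. The nucleoside transporter gene SLC29A1 rose by 3.69 ± 0.19 (log2, SD, n = 2 calves), the glutamine transporter gene SLC1A5 by 2.65 ± 0.16 and the monocarboxylate transporter gene SLC16A1 by 2.65 ± 0.14. The transcriptional regulators ID2 (3.04 ± 0.12, with 2.08 and 3.99 for its probe sets) and NFIL3 (2.71 ± 0.40) rose, as did IL4R, a receptor chain for IL4 and IL13 (2.67 ± 0.05, with 2.24 and 3.09 for its probe sets), AGO2, an effector of RNA silencing (3.18 ± 0.02), and USP12 (3.22 ± 0.28). Limma's adjusted p lay at or below 2.31e-05 for each of these.

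Some T cell genes, picked after their values had been seen, differed between the calves. CD8B was higher in calf 303 by 2.30 with PBS and 2.29 with APP on the log2 scale, TRGC4 by 1.66 and 2.05, CD8A by 1.91 and 1.26, LCK by 1.54 and 1.48, CD96 by 1.48 and 1.47, and CD2 by 1.09 and 1.12 (adjusted p at or below 0.00673 in limma's test for each). The probe sets of 3 of these genes differed in size, from 0.34 to 3.01 for TRGC4, 0.80 to 1.89 for LCK and 0.26 to 1.91 for CD2. CD3E differed by 0.07 (adjusted p = 0.767), WC1.3 by -0.25 (adjusted p = 0.26) and CD4 by -0.11 (adjusted p = 0.607). As lists, the gamma delta T cell identity genes (2 of 18 called) and the alpha beta T and NK cell genes (2 of 11 called) did not pass the test between the calves (camera adjusted p = 0.188 for each, adjusted p = 0.817 with an estimated correlation), and TRGC4 and CD96 stand in neither. The list test ran downward in calf 303 for NRF2 antioxidant genes (median -0.26, camera adjusted p = 6.62e-06) and for unfolded protein and amino acid response genes (median -0.16, camera adjusted p = 0.000153), both at adjusted p = 0.817 with an estimated correlation. Of the 26 NRF2 genes 1 was called lower and 1 higher, and of the 27 unfolded protein genes 1 was called lower, so that nearly all members did not pass on their own.

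TNF, CCL4, CXCL8 and CXCL2, which rose with APP, are also induced by endotoxin in monocytes. A candidate explanation is a response of remaining myeloid cells to endotoxin in the extract, against a response of the gamma delta T cells to APP. Which cells responded, and to which part of the extract, are separate questions, so other pairings remain open too. A set of 10 monocyte endotoxin response genes had a median change of 0.134, with IL1B at 0.14 and IL6 at 0.02. The highest was CSF3, which rose by 0.307 (adjusted p = 0.0321 in limma's test). The lowest was SOD2, which fell by 0.46 (-0.71 in calf 301 and -0.21 in calf 303, adjusted p = 0.0244 in limma's test). All 10 also stand in the cytokine, chemokine or NF-kappaB lists. CCL20, CCL3, CCL2 and IL1RN of those lists, which rose, were not put into the set, so its median depends on the choice of genes. The values of the 10 genes are small beside those of the 4 genes. The fall of SOD2 does not decide, because it is measured over all sorted cells, of which myeloid cells could be only a small share. Levels are not kept, and the members that did not pass would look the same below background in both treatments, so the explanations cannot be told apart. The cells were sorted to over 97% purity. The monocyte marker gene CD14 was higher with APP by 0.52 in calf 301 and 0.40 in calf 303. Of 23 monocyte and dendritic cell genes, 10 rose and 2 fell (camera adjusted p = 0.0134 at the preset correlation), with CD68 up by 1.90 and 2.71.

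IGHM, JCHAIN, BLK, CD79A and MS4A1 fell with APP, by 2.31, 1.33, 1.04, 0.80 and 0.56 (-1.08 and -0.04 for the probe sets of MS4A1), while the other 3 measured B cell genes did not fall, with POU2AF1 at 3.81, BLNK at 0.26 (adjusted p = 0.0739) and CR2 at 0.12 (adjusted p = 0.36). A lower share of B cells among the APP cells may account for the 5 falls, though not for the rise of POU2AF1, and so may a change of these transcripts within the cells present. A chosen set of 3 class II genes of the major histocompatibility complex, abundant in B cells, rose by a median of 0.38, against the fall that fewer B cells would bring. They were BOLA-DRA (0.47), BOLA-DRB3 (0.38) and BOLA-DQA5 (0.37), and BOLA-DYA, also measured, was not in the set. Bovine gamma delta T cells and monocytes can express class II genes too, and without levels the source of that signal is open, so the explanations cannot be told apart.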
